A study of Mus musculus with 24 samples.

How the data were processed

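The series holds 24 arrays of sorted endothelial cells, 8 each from wild-type adult hindbrain, Shh medulloblastoma and Wnt medulloblastoma of mice of mixed strain background. Per the labels, tissue was dissociated with papain, cells were sorted with magnetic beads and Cd105 and Cd144 antibodies, RNA was extracted with Qiagen columns, and biotinylated cRNA was hybridised to Affymetrix arrays. The deposited values are on a log2 scale, 1 value per probe set and array, as their range shows. The authors name Partek 6.6 without its role, and summarisation, background correction and normalization are not given in the sources used here. The deposited table held 41345 probe sets, 190 of them controls, 23521 with 1 gene symbol in the platform annotation, 1814 with several and 15820 with none. Of the single symbols, 23328 (99.2%) matched a gene ID of the reference gene table. Genomic positions are not given because the build of the array is not named.

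Genes with exactly 1 symbol were kept, each represented by its probe set with the highest mean over all arrays, which left 22180 genes, 1082 of them with more than 1 probe set. Deposited values were used without further normalization. A linear model with the group as its single factor was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, 21 residual degrees of freedom), with contrasts Wnt minus hindbrain, Shh minus hindbrain and Wnt minus Shh. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The test is limma's moderated one, and its standard errors follow from the shrunken variances.

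Gene lists and marker lists of cell types were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast. The list of red blood cell markers had 2 measured members, under the minimum of 5, and was not tested, which left 31. Some genes are in more than 1 list. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, were run beside it. Named genes were, in each comparison, the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, passing over genes without a proper name, then the 2 strongest risers and fallers of each list, or the 2 with the smallest p, and a fixed set of genotype, sort antigen, barrier and Wnt genes. The text names part of these, chosen after their values had been seen.

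The gene test was run on data simulated with the spread of the arrays. Its counts need not hold where spread differs by group, as for Mfsd2a. Of 50 genes shifted by a log2 change of 0.5, 1, 1.5 and 2, 33, 46, 49, 50 were recovered for Wnt minus hindbrain, 33, 47, 49, 50 for Shh minus hindbrain and 24, 44, 50, 50 for Wnt minus Shh, with 8, 38 and 4 false calls. When a single list was shifted in simulated data, camera with the preset correlation found it. It also called 11 unshifted lists, against 0 with an estimated correlation. Over 100 shuffles of unchanged arrays, the preset correlation called a median of 9 lists (0 to 18) and the estimated one a median of 0 (0 to 2). A list call with the preset correlation alone is therefore weak evidence, and the p with an estimated correlation stands beside it.

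Genes called in both tumour groups were counted and set beside simulations of unchanged tumour groups that share the hindbrain arrays, and beside splits of the hindbrain arrays into sets of 4. Alternatives were every probe set on its own, the mean of the probe sets of a gene, quantile normalization, a shift of each array to the same median, leaving out dim genes, a variance trend, array weights, fits to the compared groups alone, a block by replicate number, the endothelial marker mean as a covariate, and leaving out each array. Values relative to the endothelial markers, a fit without the Wnt arrays 1 and 8, and camera with both the endothelial covariate and an estimated correlation were added after the data had been seen. Array numbers do not pair the samples: correlations between arrays of the same number ran from -0.146 to 0.282. Probe sets with several or no gene symbols were left out of the gene tests because they name no single gene, and Trp53 was left out for the same reason.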

Results

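Gene expression was measured with Affymetrix mouse arrays in cells sorted from adult hindbrain and from medulloblastomas, tumours of the cerebellum and brainstem region, of a Shh and a Wnt mouse model. The comparison asks how the expression of blood vessel cells differs between normal brain and each kind of tumour. Tissue was dissociated with papain, and cells were taken with magnetic beads through Cd144, encoded by Cdh5, and Cd105, encoded by Eng, which are surface proteins of endothelium. The Shh mice carried Ptch+/- and Ink4c-/- alleles (Ink4c is encoded by Cdkn2c), the Wnt mice carried Blbp-Cre with altered Ctnnb1, Trp53 and Pik3ca alleles, and the hindbrain was wild type. Each group held 8 arrays, called biological replicates in the labels. The array medians lay between 5.96 and 6.18 on the log2 scale, and the number of arrays limits the precision of each value. The means of 92 control probe sets for ERCC sequences, which are not mouse genes, had a median of 3.96 and a 95th percentile of 5.24, the background against which dim genes are read here.

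In a principal component analysis of 22180 genes, the first component held 46.9% of the variance and the second 20.6%. Scores on the first component ran from -59.3 to -44 in hindbrain, -23.7 to -0.876 in Shh and 40 to 74.6 in Wnt arrays, so the groups did not overlap. Values after ± are standard errors of log2 fold changes, or standard deviations (n = 8) where group means are given. Unless a unit is named, values in parentheses after a gene are log2 fold changes. The median of a list is that of the log2 fold changes of its members, and the p beside it is that of camera. Counts adjusted over the list alone are given where they differ from those over all genes tested. Because camera with its preset correlation called a median of 9 of 31 lists in shuffled arrays without change, its calls are weak where the p with an estimated correlation does not pass. Gene lists, the rule for naming genes and the tests of the comparisons were chosen before the data were examined. The tests of barrier minus endothelial means, the values relative to endothelial markers and the choice of which named genes to print came after. A change to or from a mean within the range of the ERCC controls has an uncertain size and rank.

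Transcripts of both sort antigens were abundant in every group. Cdh5 had a mean of 12.82 ± 0.087 in hindbrain, 12.89 ± 0.14 in Shh and 12.41 ± 0.35 in Wnt arrays (log2, SD, n = 8), and Eng 12.83 ± 0.074, 12.71 ± 0.17 and 12.09 ± 0.31. Both fell in Wnt against hindbrain, with Cdh5 (-0.41 ± 0.11, adjusted p = 0.00293) and Eng (-0.74 ± 0.10, adjusted p = 1.43e-06), and neither passed the test in Shh against hindbrain, with Cdh5 (0.069 ± 0.11, adjusted p = 0.658) and Eng (-0.12 ± 0.10, adjusted p = 0.372). Averaged over 16 endothelial markers, the level was 11.56 ± 0.10 in hindbrain, 11.38 ± 0.20 in Shh and 10.51 ± 0.46 in Wnt arrays, lowest in Wnt arrays 8 (9.77) and 1 (9.95). All 16 endothelial markers fell in Wnt against hindbrain, with a median of -0.92 (adjusted p = 1.18e-07, and adjusted p = 0.239 with an estimated correlation), among them Tek (-1.91 ± 0.20) and Flt1 (-1.94 ± 0.19). In Shh against hindbrain, 3 fell, Flt1 and Tek among them, and 13 did not pass the test (2 down adjusted over the list alone), with a median of -0.12 (adjusted p = 0.251). In Wnt against Shh, 14 fell and 2 did not pass the test (15 down adjusted over the list alone), with a median of -0.98 (adjusted p = 2.68e-08, and adjusted p = 0.372 with an estimated correlation), among them Erg (-1.38 ± 0.18). The lower endothelial marker level of the Wnt arrays stands beside every change reported for them.

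Genes altered in the models were measured with probe sets whose position relative to the altered part is not known, so these values check no genotype. Ptch1, the receptor of Shh, did not pass the test in Shh (-0.14 ± 0.21, adjusted p = 0.643) or Wnt arrays (0.072 ± 0.21, adjusted p = 0.819) against hindbrain, nor between them (0.21 ± 0.21, adjusted p = 0.473). Cdkn2c, a cell cycle inhibitor, rose in Wnt arrays (1.72 ± 0.19, adjusted p = 5.73e-08), rose less in Shh arrays (0.53 ± 0.19, adjusted p = 0.0332) and was higher in Wnt than Shh (1.19 ± 0.19, adjusted p = 2.43e-05). The Shh call of Cdkn2c was lost without hindbrain replicates 3 (0.51), 4 (0.48), 8 (0.43), Shh replicates 1 (0.52), 2 (0.47), 5 (0.52), 8 (0.50). Ctnnb1, which encodes beta-catenin, fell in Wnt arrays (-0.24 ± 0.072, adjusted p = 0.00788), with -0.16 ± 0.072, adjusted p = 0.0859 in Shh arrays, where it passed the test without hindbrain replicate 6 (-0.19), Shh replicate 5 (-0.19), and -0.081 ± 0.072, adjusted p = 0.415 between the tumours. Pik3ca, a kinase subunit, gave 0.0076 ± 0.069, adjusted p = 0.941 in Wnt against hindbrain, 0.091 ± 0.069, adjusted p = 0.322 in Shh against hindbrain and -0.083 ± 0.069, adjusted p = 0.381 in Wnt against Shh. Trp53 was not analysed here.

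The first comparison sets cells from Wnt tumours against those from hindbrain. Most transporters (21 of 24) and junction genes (9 of 14) of the blood-brain barrier were lower in the Wnt arrays, while Plvap, a protein of fenestrated vessels, was higher (4.09 ± 0.34, adjusted p = 4.47e-10). Most secreted antagonists of Wnt signalling were higher (11 of 13), led by Wif1 (6.69 ± 0.29, adjusted p = 4.49e-15), a secreted protein that binds Wnt ligands. Most genes of the interstitial matrix (17 of 18), the basement membrane (11 of 17) and the cell cycle (25 of 26) rose, and most microglial (16 of 20), interferon response (19 of 21) and immediate early genes (15 of 16) fell. Except for the antagonists, the calls of these lists by camera were lost with an estimated correlation (adjusted p from 0.118 to 0.387).

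Of 24 barrier transporters, 0 rose, 21 fell and 3 did not pass the test (0 up and 22 down adjusted over the list alone), with a median of -2.23 (adjusted p = 8.68e-14, and adjusted p = 0.169 with an estimated correlation). Among the fallers were the organic anion transporter Slc22a8 (-4.89 ± 0.30), the iron exporter Slc40a1 (-4.22 ± 0.23), the lipid transporter Mfsd2a (-2.89 ± 0.35), the efflux pump Abcb1a (-2.49 ± 0.23) and the glucose transporter Slc2a1 (-1.41 ± 0.19). Of 14 barrier junction genes, 2 rose, 9 fell and 3 did not pass the test, with a median of -1.06 (adjusted p = 0.000771, and adjusted p = 0.239 with an estimated correlation). Lsr (-2.69 ± 0.22), Ocln (-2.36 ± 0.21) and Cldn5 (-2.06 ± 0.20) fell, and Marveld3 (0.91 ± 0.11) rose. Of 15 genes of fenestrated and peripheral vessels, 9 rose, 2 fell and 4 did not pass the test, with a median of 1.71 (adjusted p = 0.00432, and adjusted p = 0.217 with an estimated correlation). Beside Plvap, Aqp1 (4.41 ± 0.42) and Esm1 (3.35 ± 0.30) rose and Tcf15 (-1.94 ± 0.12) fell. Of 8 genes of caveolae, 1 rose, 5 fell and 2 did not pass the test, with a median of -0.82 (adjusted p = 0.0185, and adjusted p = 0.356 with an estimated correlation). Cav1 (-1.33 ± 0.16) and Cav2 (-1.48 ± 0.11) fell. The endothelial markers of these arrays fell too, with a median of -0.92, and barrier transporters fell further: their mean minus that of the endothelial markers was 0.076 ± 0.058 in hindbrain and -1.17 ± 0.46 in Wnt arrays (SD, n = 8), a difference of -1.24 (two-sided exact permutation p = 0.000155, the smallest that 12870 splits can give).

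**Figure D1:**
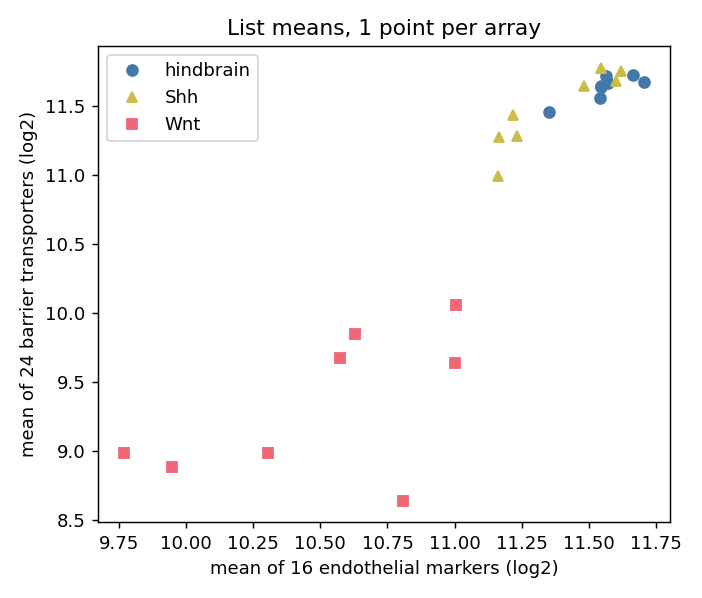
Mean log2 value of 24 barrier transporters against that of 16 endothelial markers, 1 point per array, with colour and shape for the group. Wnt arrays lie low on both axes, with a lowest endothelial mean of 9.77, and Shh and hindbrain arrays lie together at the upper right.

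Of 13 secreted Wnt antagonists, 11 rose, 0 fell and 2 did not pass the test (12 up and 0 down adjusted over the list alone), with a median of 1.81 (adjusted p = 5.86e-06, and adjusted p = 0.00812 with an estimated correlation). This was the single list of the comparison still called with an estimated correlation. Sostdc1 (4.45 ± 0.35) and Dkk1 (1.81 ± 0.36) rose beside Wif1. Of 17 Wnt beta-catenin targets, 12 rose, 5 fell and 0 did not pass the test, with a median of 1.11 (adjusted p = 0.00351, and adjusted p = 0.217 with an estimated correlation). Rnf43 (4.31 ± 0.19), Sp5 (3.20 ± 0.15) and Axin2 (1.21 ± 0.12) rose. RNA of tumour cells with altered Ctnnb1 was not tested as a source. The endothelial transcription factors Foxq1 (-3.39 ± 0.20) and Sox17 (-2.45 ± 0.19) and the beta-catenin partner Lef1 (-0.37 ± 0.12) fell. Of 9 Wnt receptors of brain endothelium, 0 rose, 6 fell and 3 did not pass the test, with a median of -0.34 (adjusted p = 0.00804, and adjusted p = 0.239 with an estimated correlation). Fzd6 (-1.48 ± 0.15) and Adgra2 (-0.99 ± 0.13) fell. Of 10 Shh pathway genes, 7 rose, 0 fell and 3 did not pass the test, with a median of 2.02 (adjusted p = 2e-05, and adjusted p = 0.217 with an estimated correlation). Hhip (4.65 ± 0.32) and Gli3 (2.94 ± 0.15) rose, Hhip from a hindbrain mean within the range of the ERCC controls.

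Of 22 genes of tip cells and sprouting, 11 rose, 8 fell and 3 did not pass the test, with a median of 0.18 (adjusted p = 0.239). Igfbp3 (3.51 ± 0.22) and Lamb1 (3.14 ± 0.18) rose and Pdgfb (-1.89 ± 0.19) fell. Of 13 Notch pathway genes, 2 rose, 9 fell and 2 did not pass the test (2 up and 10 down adjusted over the list alone), with a median of -0.51 (adjusted p = 0.00439, and adjusted p = 0.259 with an estimated correlation). The ligand Jag2 (-2.17 ± 0.14) fell. Of 17 BMP and TGF-beta genes, 5 rose, 9 fell and 3 did not pass the test (6 up and 9 down adjusted over the list alone), with a median of -0.44 (adjusted p = 0.259). Bmp4 (2.93 ± 0.16) rose and the receptor Acvrl1 (-1.48 ± 0.14) fell. Of 14 arterial genes, 3 rose, 8 fell and 3 did not pass the test, with a median of -1.13 (adjusted p = 0.00114, and adjusted p = 0.217 with an estimated correlation). Gkn3 (-4.72 ± 0.23) and Edn1 (-3.92 ± 0.41) fell. Of 11 venous genes, 3 rose, 3 fell and 5 did not pass the test (3 up and 4 down adjusted over the list alone), with a median of -0.19 (adjusted p = 0.942), while the mean was 0.080 and the set test pointed down. The apelin receptor Aplnr (2.69 ± 0.19) rose and Slc38a5 (-2.94 ± 0.31) fell. Of 12 genes of leukocyte adhesion, 3 rose, 5 fell and 4 did not pass the test, with a median of -0.23 (adjusted p = 0.396). Sele (2.74 ± 0.47) rose and Icam1 (-2.36 ± 0.25) fell. Of 17 basement membrane genes, 11 rose, 4 fell and 2 did not pass the test, with a median of 0.82 (adjusted p = 0.011, and adjusted p = 0.387 with an estimated correlation). Tinagl1 (-1.39 ± 0.27) fell. Of 18 genes of the interstitial matrix, 17 rose, 0 fell and 1 did not pass the test, with a median of 2.10 (adjusted p = 1.16e-12, and adjusted p = 0.118 with an estimated correlation). Postn (4.89 ± 0.20) and Tnc (4.48 ± 0.36) rose. Of 26 cell cycle genes, 25 rose, 1 fell and 0 did not pass the test, with a median of 1.81 (adjusted p = 7.22e-13, and adjusted p = 0.229 with an estimated correlation). Ccna2 (3.55 ± 0.23) and Cdk1 (3.40 ± 0.22) rose and Pcna (-0.33 ± 0.11) fell. Of 17 genes of hypoxia and glycolysis, 5 rose, 5 fell and 7 did not pass the test, with a median of -0.11 (adjusted p = 0.942). Vegfa (2.08 ± 0.21) rose and Ndrg1 (-1.75 ± 0.23) fell. Of 21 genes of interferon response and antigen presentation, 0 rose, 19 fell and 2 did not pass the test, with a median of -1.56 (adjusted p = 2.59e-09, and adjusted p = 0.217 with an estimated correlation). Ifit1 (-2.72 ± 0.33) and Gbp3 (-2.43 ± 0.23) fell. Of 16 immediate early and heat shock genes, 0 rose, 15 fell and 1 did not pass the test, with a median of -1.41 (adjusted p = 9.46e-08, and adjusted p = 0.217 with an estimated correlation). The chaperones Hspa1a (-2.60 ± 0.45) and Hspa1b (-2.61 ± 0.57) fell.

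Markers of other cells moved in both directions in the same arrays. Of 10 fibroblast markers, 9 rose, 0 fell and 1 did not pass the test, with a median of 1.80 (adjusted p = 2.25e-05, and adjusted p = 0.171 with an estimated correlation). Islr (2.42 ± 0.31) and Ogn (2.37 ± 0.32) rose, beside the matrix genes. Of 12 pericyte markers, 0 rose, 7 fell and 5 did not pass the test, with a median of -0.50 (adjusted p = 0.00804, and adjusted p = 0.43 with an estimated correlation). Atp13a5 (-5.01 ± 0.58) and Vtn (-2.52 ± 0.44) fell. Of 6 smooth muscle markers, 1 rose, 2 fell and 3 did not pass the test, with a median of -0.30 (adjusted p = 0.435). Myh11 (-2.12 ± 0.15) fell. Of 20 microglia and macrophage markers, 0 rose, 16 fell and 4 did not pass the test (2 up and 16 down adjusted over the list alone), with a median of -1.71 (adjusted p = 1.51e-05, and adjusted p = 0.356 with an estimated correlation). P2ry12 (-3.45 ± 0.37) and Itgam (-2.73 ± 0.31) fell, beside the immediate early genes. Of 9 lymphocyte markers, 0 rose, 6 fell and 3 did not pass the test, with a median of -0.46 (adjusted p = 0.0235, and adjusted p = 0.33 with an estimated correlation). Cd79b (-1.07 ± 0.20) fell. Of 13 neuron markers, 4 rose, 5 fell and 4 did not pass the test, with a median of -0.12 (adjusted p = 0.4). Snap25 (-2.33 ± 0.38) fell. Of 16 markers of granule neuron precursors, 3 rose, 4 fell and 9 did not pass the test, with a median of -0.093 (adjusted p = 0.942), while the mean was 0.071 and the set test pointed down. Sox11 (2.66 ± 0.21) rose and Zic2 (-2.33 ± 0.31) fell. Of 12 astrocyte markers, 3 rose, 2 fell and 7 did not pass the test, with a median of -0.15 (adjusted p = 0.942), while the mean was 0.015 and the set test pointed up. Gja1 (1.74 ± 0.15) rose and S100b (-1.93 ± 0.21) fell. Of 14 oligodendrocyte lineage markers, 2 rose, 8 fell and 4 did not pass the test, with a median of -0.51 (adjusted p = 0.00977, and adjusted p = 0.239 with an estimated correlation). Mbp (-2.75 ± 0.15) fell and Pdgfra (2.48 ± 0.33) rose. Of 8 choroid plexus and ependyma markers, 2 rose, 5 fell and 1 did not pass the test, with a median of -0.65 (adjusted p = 0.633), while the mean was 0.12 and the set test pointed down.

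Of 22180 genes, 5152 were higher and 4888 lower in Wnt arrays, 1505 and 1173 of them by at least 2-fold. The share of higher genes among those called was 51.3%, against 59.9% with each array shifted to the same median and 97.3% relative to the endothelial marker mean. The named genes with the largest rises and no overlap between the groups included Chrdl1 (6.18 ± 0.37, adjusted p = 1.26e-12), Wnt16 (6.15 ± 0.23, adjusted p = 2.16e-16), A2m (6.11 ± 0.44, adjusted p = 3.35e-11) and Fabp5 (5.87 ± 0.22, adjusted p = 2.38e-16), Mybpc1 (5.85 ± 0.35), Srpx2 (5.79 ± 0.19) and P2rx2 (5.62 ± 0.29). The largest falls included Sgpp2 (-5.30 ± 0.17, adjusted p = 1.12e-17) and Il1a (-5.22 ± 0.49, adjusted p = 2.82e-09), with Far2 (-4.58 ± 0.33), Tecrl (-4.42 ± 0.33) and Car4 (-4.29 ± 0.44) after them. Hindbrain means of Chrdl1 and P2rx2 and the Wnt mean of Tecrl lay within the range of the ERCC controls. Among 31 lists, camera called 21 with the preset correlation (8 up, 13 down), 1 with an estimated correlation and 6 with an estimated correlation before adjustment, and fry called 26. With the endothelial marker mean as a covariate, 2288 genes were higher and 1976 lower, the signs of Cdh5 (0.32, adjusted p = 0.0247), Tinagl1 (0.24, adjusted p = 0.679) and Vtn (0.21, adjusted p = 0.839) turned, and the calls of Cdkn2c (0.69, adjusted p = 0.0682), Ctnnb1 (-0.18, adjusted p = 0.404), Eng (-0.040, adjusted p = 0.824), Slc2a1 (-0.57, adjusted p = 0.193), Dkk1 (1.63, adjusted p = 0.0971), Lef1 (-0.22, adjusted p = 0.597), Cav1 (-0.40, adjusted p = 0.158), Adgra2 (-0.28, adjusted p = 0.309), Sele (2.19, adjusted p = 0.0883), Ndrg1 (-0.68, adjusted p = 0.183), Hspa1b (-1.39, adjusted p = 0.42), Hspa1a (-1.64, adjusted p = 0.18), Snap25 (-1.93, adjusted p = 0.0578), Zic2 (-0.39, adjusted p = 0.468), Pdgfra (1.60, adjusted p = 0.0576) and Ttr (-1.89, adjusted p = 0.515) ended, as did those of the lists of barrier junctions, caveolae, Wnt receptors of brain endothelium, Notch pathway, endothelial, pericyte and lymphocyte genes. Taken relative to the endothelial marker mean, every log2 fold change is larger by 1.06, which turns the sign of the medians of 16 lists, among the lists called those of caveolae, Wnt receptors of brain endothelium, Notch pathway, endothelial, pericyte, lymphocyte and oligodendrocyte lineage genes, but not that of the barrier transporters, while the median of the barrier junction genes is then -0.0062. Of the genes printed for this comparison, it turned the direction of Ctnnb1 (0.82, adjusted p = 3.71e-05), Cdh5 (0.65, adjusted p = 8.38e-06), Eng (0.31, adjusted p = 0.0117), Lef1 (0.68, adjusted p = 0.000794), Adgra2 (0.064, adjusted p = 0.647) and Pcna (0.73, adjusted p = 0.00206).

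**Figure D2:**
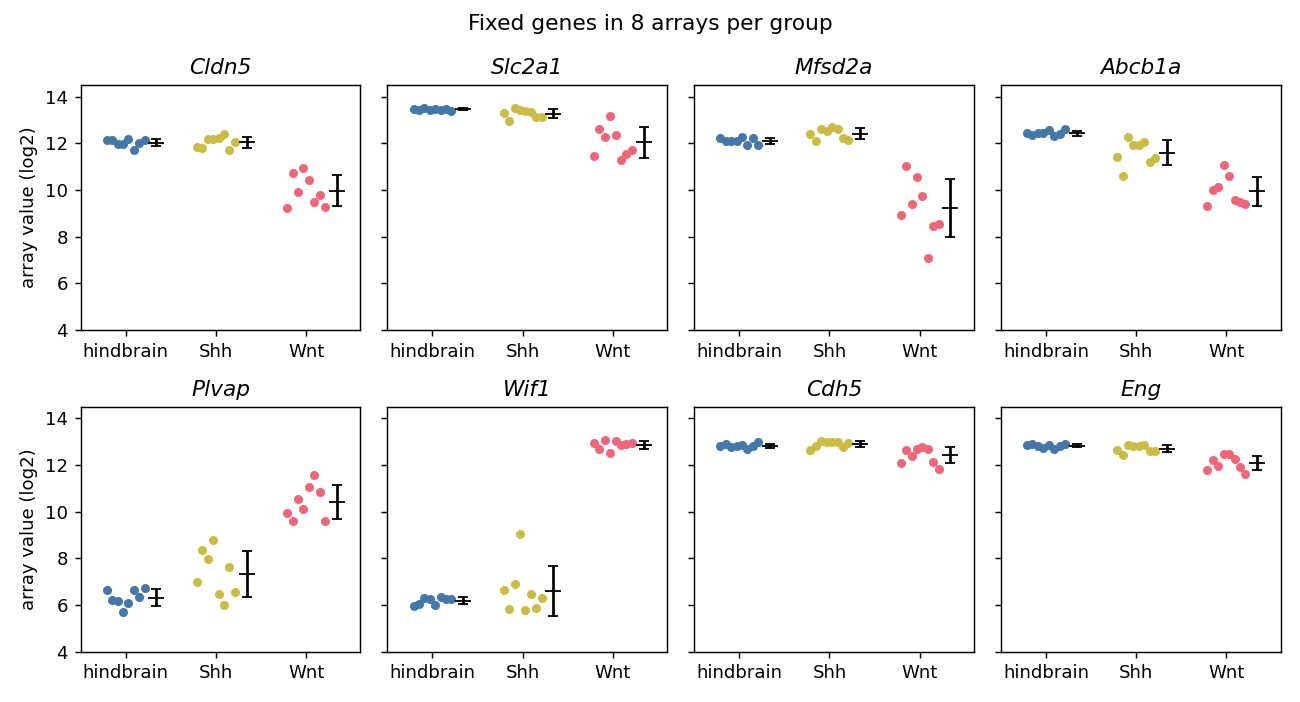
Array values (log2) of 8 genes in hindbrain, Shh and Wnt arrays, 1 point per array, with the group mean and SD as a bar at the right of the points. Cldn5, Slc2a1, Mfsd2a and Abcb1a are lower and Plvap and Wif1 higher in Wnt than in hindbrain arrays without overlap, and Cdh5 and Eng move less, down as deposited and up relative to the endothelial markers (0.65 and 0.31). Cdh5 and Eng are among those markers, so their upward turn follows in part from the reference.

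In Shh against hindbrain, most barrier transporters and junction genes did not pass the test, like most genes (37.8% passed). Cldn5 (0.019 ± 0.20, adjusted p = 0.951), Mfsd2a (0.30 ± 0.35, adjusted p = 0.524) and Slc2a1 (-0.19 ± 0.19, adjusted p = 0.448) did not pass. These standard errors include the wider spread of Wnt arrays (Mfsd2a SD 1.25, hindbrain 0.13). Fitted without Wnt arrays, Mfsd2a and Slc2a1 passed (adjusted p = 0.0167 and 0.0425). Basement membrane (13 of 17), cell cycle (25 of 26), sprouting (11 of 22) and venous genes (6 of 11) rose. So did Apln (4.57 ± 0.24, adjusted p = 6.71e-13) and Ackr1 (4.21 ± 0.32, adjusted p = 3.51e-10), encoding the apelin receptor ligand and a chemokine receptor of venules. Markers of granule neuron precursors (12 of 16) rose too, and smooth muscle (5 of 6), arterial (7 of 14) and immediate early genes (16 of 16) fell. Camera's calls of these lists were lost with an estimated correlation (adjusted p from 0.0856 to 0.194).

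Of 24 barrier transporters, 3 rose, 5 fell and 16 did not pass the test, with a median of -0.11 (adjusted p = 0.577). Slc38a5 (0.97 ± 0.31) and the lactate transporter Slc16a1 (0.73 ± 0.21) rose, and Slc6a6 (-1.85 ± 0.15) and Abcb1a (-0.84 ± 0.23) fell. The barrier transporter mean minus the endothelial marker mean differed by 0.029 between Shh and hindbrain arrays (two-sided exact permutation p = 0.593), which does not show equal levels. Of 14 barrier junction genes, 0 rose, 5 fell and 9 did not pass the test, with a median of -0.11 (adjusted p = 0.12). Ocln (-0.75 ± 0.21) fell. Of 15 genes of fenestrated and peripheral vessels, 7 rose, 1 fell and 7 did not pass the test (8 up and 1 down adjusted over the list alone), with a median of 0.87 (adjusted p = 0.0701, and adjusted p = 0.371 with an estimated correlation), and it passed the test at the preset correlation without Shh replicates 5 (0.93), 6 (1.01). Esm1 (2.80 ± 0.30) and Plvap (1.02 ± 0.34) rose and Tcf15 (-2.20 ± 0.12) fell, and the call of Plvap was lost without Shh replicates 2 (0.87), 4 (0.82). Of 8 genes of caveolae, 1 rose, 5 fell and 2 did not pass the test, with a median of -0.60 (adjusted p = 0.00196, and adjusted p = 0.239 with an estimated correlation). Cavin2 (-1.41 ± 0.15) fell. Of 13 secreted Wnt antagonists, 6 rose, 0 fell and 7 did not pass the test, with a median of 0.80 (adjusted p = 0.00762, and adjusted p = 0.126 with an estimated correlation). Draxin (3.33 ± 0.24) and Sfrp1 (3.13 ± 0.43) rose, with Wif1 (0.42 ± 0.29, adjusted p = 0.275) and Dkk1 (-0.27 ± 0.36, adjusted p = 0.592) not passing the test. Of 17 Wnt beta-catenin targets, 4 rose, 5 fell and 8 did not pass the test (5 up and 5 down adjusted over the list alone), with a median of 0.084 (adjusted p = 0.696), while the mean was -0.13 and the set test pointed down. Notum (-2.26 ± 0.22), Axin2 (-0.72 ± 0.12) and Lef1 (-0.70 ± 0.12) fell and Ccnd1 (0.87 ± 0.13) rose. Of 9 Wnt receptors of brain endothelium, 0 rose, 3 fell and 6 did not pass the test, with a median of -0.16 (adjusted p = 0.0723, and adjusted p = 0.462 with an estimated correlation), and it passed the test at the preset correlation without hindbrain replicate 6 (-0.19), Shh replicates 3 (-0.18), 5 (-0.19). Reck (-1.46 ± 0.18) fell. Of 10 Shh pathway genes, 7 rose, 0 fell and 3 did not pass the test, with a median of 0.77 (adjusted p = 0.00128, and adjusted p = 0.239 with an estimated correlation). Hhip (2.01 ± 0.32) and Gli2 (1.83 ± 0.24) rose, Hhip from a hindbrain mean within the range of the ERCC controls.

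Of 22 genes of tip cells and sprouting, 11 rose, 1 fell and 10 did not pass the test, with a median of 0.56 (adjusted p = 7.63e-06, and adjusted p = 0.132 with an estimated correlation). Lamb1 (3.50 ± 0.18) rose and Flt1 (-0.95 ± 0.19) fell, beside Tek (-0.79 ± 0.20) among the endothelial markers. Of 13 Notch pathway genes, 1 rose, 5 fell and 7 did not pass the test (1 up and 6 down adjusted over the list alone), with a median of -0.24 (adjusted p = 0.09). Hey2 (-1.06 ± 0.15) fell. Of 17 BMP and TGF-beta genes, 3 rose, 12 fell and 2 did not pass the test, with a median of -0.60 (adjusted p = 0.00231, and adjusted p = 0.127 with an estimated correlation). Smad6 (-1.78 ± 0.20) fell and Tgfbi (1.53 ± 0.27) rose. Of 14 arterial genes, 1 rose, 7 fell and 6 did not pass the test (1 up and 9 down adjusted over the list alone), with a median of -0.74 (adjusted p = 0.000208, and adjusted p = 0.127 with an estimated correlation). Gkn3 (-4.24 ± 0.23) and Alpl (-3.56 ± 0.26) fell. Of 11 venous genes, 6 rose, 0 fell and 5 did not pass the test, with a median of 0.65 (adjusted p = 0.000686, and adjusted p = 0.194 with an estimated correlation). Aplnr (3.37 ± 0.19) and Selp (2.16 ± 0.46) rose. Of 12 genes of leukocyte adhesion, 5 rose, 4 fell and 3 did not pass the test, with a median of -0.091 (adjusted p = 0.696), while the mean was 0.41 and the set test pointed up. Cxcl12 (-1.68 ± 0.25) fell. Of 17 basement membrane genes, 13 rose, 3 fell and 1 did not pass the test, with a median of 1.28 (adjusted p = 9.07e-07, and adjusted p = 0.127 with an estimated correlation). Nid1 (1.79 ± 0.18) rose and Tinagl1 (-2.51 ± 0.27) fell. Of 18 genes of the interstitial matrix, 17 rose, 0 fell and 1 did not pass the test, with a median of 1.68 (adjusted p = 7.61e-14, and adjusted p = 0.0856 with an estimated correlation). Timp1 (3.48 ± 0.22) and Postn (3.28 ± 0.20) rose. Of 26 cell cycle genes, 25 rose, 0 fell and 1 did not pass the test, with a median of 2.18 (adjusted p = 1.13e-21, and adjusted p = 0.127 with an estimated correlation). Ccna2 (3.71 ± 0.23) and Cdk1 (3.63 ± 0.22) rose. Of 17 genes of hypoxia and glycolysis, 5 rose, 6 fell and 6 did not pass the test (6 up and 7 down adjusted over the list alone), with a median of -0.091 (adjusted p = 0.467). Adm (1.58 ± 0.24) rose and Ndrg1 (-2.44 ± 0.23) fell. Of 21 genes of interferon response and antigen presentation, 0 rose, 12 fell and 9 did not pass the test (0 up and 13 down adjusted over the list alone), with a median of -0.62 (adjusted p = 0.000516, and adjusted p = 0.462 with an estimated correlation). Ifit1 (-1.66 ± 0.33) and Mx2 (-1.48 ± 0.20) fell. Of 16 immediate early and heat shock genes, 0 rose, 16 fell and 0 did not pass the test, with a median of -1.04 (adjusted p = 1.03e-09, and adjusted p = 0.132 with an estimated correlation). Hspa1b (-3.66 ± 0.57) and Hspa1a (-3.23 ± 0.45) fell.

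Markers of other cells moved in both directions. Of 16 markers of granule neuron precursors, 12 rose, 0 fell and 4 did not pass the test (13 up and 1 down adjusted over the list alone), with a median of 1.76 (adjusted p = 2.66e-09, and adjusted p = 0.126 with an estimated correlation). Nhlh1 (3.59 ± 0.29) and Dcx (3.54 ± 0.25) rose from hindbrain means within the range of the ERCC controls. Of 6 smooth muscle markers, 0 rose, 5 fell and 1 did not pass the test, with a median of -1.57 (adjusted p = 0.000372, and adjusted p = 0.0856 with an estimated correlation). Myh11 (-2.65 ± 0.15) and Tagln (-1.67 ± 0.19) fell, beside the arterial genes. Of 10 fibroblast markers, 8 rose, 2 fell and 0 did not pass the test, with a median of 1.49 (adjusted p = 0.00088, and adjusted p = 0.174 with an estimated correlation). Lum (2.09 ± 0.29) and Col1a1 (2.09 ± 0.28) rose and Ogn (-1.65 ± 0.32) and Fmod (-1.26 ± 0.27) fell. Of 12 pericyte markers, 1 rose, 2 fell and 9 did not pass the test, with a median of -0.16 (adjusted p = 0.699). Notch3 (-0.73 ± 0.21) fell. Of 20 microglia and macrophage markers, 2 rose, 13 fell and 5 did not pass the test, with a median of -0.92 (adjusted p = 0.00063, and adjusted p = 0.462 with an estimated correlation). P2ry12 (-2.94 ± 0.37) and Tmem119 (-2.69 ± 0.22) fell and Ms4a7 (2.77 ± 0.49) and Lyz2 (1.22 ± 0.29) rose. Of 9 lymphocyte markers, 1 rose, 0 fell and 8 did not pass the test, with a median of -0.11 (adjusted p = 0.846). The gene that passed, Cd3g (0.50 ± 0.16), had a hindbrain mean of 4.96, within the range of the ERCC controls, and a Shh mean of 5.46, so a rise is not established. Of 13 neuron markers, 2 rose, 6 fell and 5 did not pass the test (3 up and 7 down adjusted over the list alone), with a median of -0.42 (adjusted p = 0.0973). Rbfox3 (0.99 ± 0.17) rose and Snhg11 (-2.01 ± 0.18) fell. Of 12 astrocyte markers, 5 rose, 1 fell and 6 did not pass the test, with a median of 0.69 (adjusted p = 0.0723, and adjusted p = 0.462 with an estimated correlation), and it passed the test at the preset correlation without hindbrain replicate 3 (0.77), Shh replicate 3 (0.80). Gfap (2.09 ± 0.32) rose. Of 14 oligodendrocyte lineage markers, 5 rose, 7 fell and 2 did not pass the test (5 up and 9 down adjusted over the list alone), with a median of -0.39 (adjusted p = 0.103). Olig2 (1.88 ± 0.33) rose and Mobp (-2.57 ± 0.19) fell. Of 8 choroid plexus and ependyma markers, 0 rose, 5 fell and 3 did not pass the test (1 up and 5 down adjusted over the list alone), with a median of -0.62 (adjusted p = 0.0701, and adjusted p = 0.475 with an estimated correlation), and it passed the test at the preset correlation without hindbrain replicates 2 (-0.67), 3 (-0.63), 4 (-0.66), 6 (-0.62), 7 (-0.68), Shh replicate 5 (-0.68). Kl (-1.60 ± 0.55) fell, a call lost without hindbrain replicates 1 (-1.22), 5 (-1.45), 8 (-1.19).

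**Figure D3:**
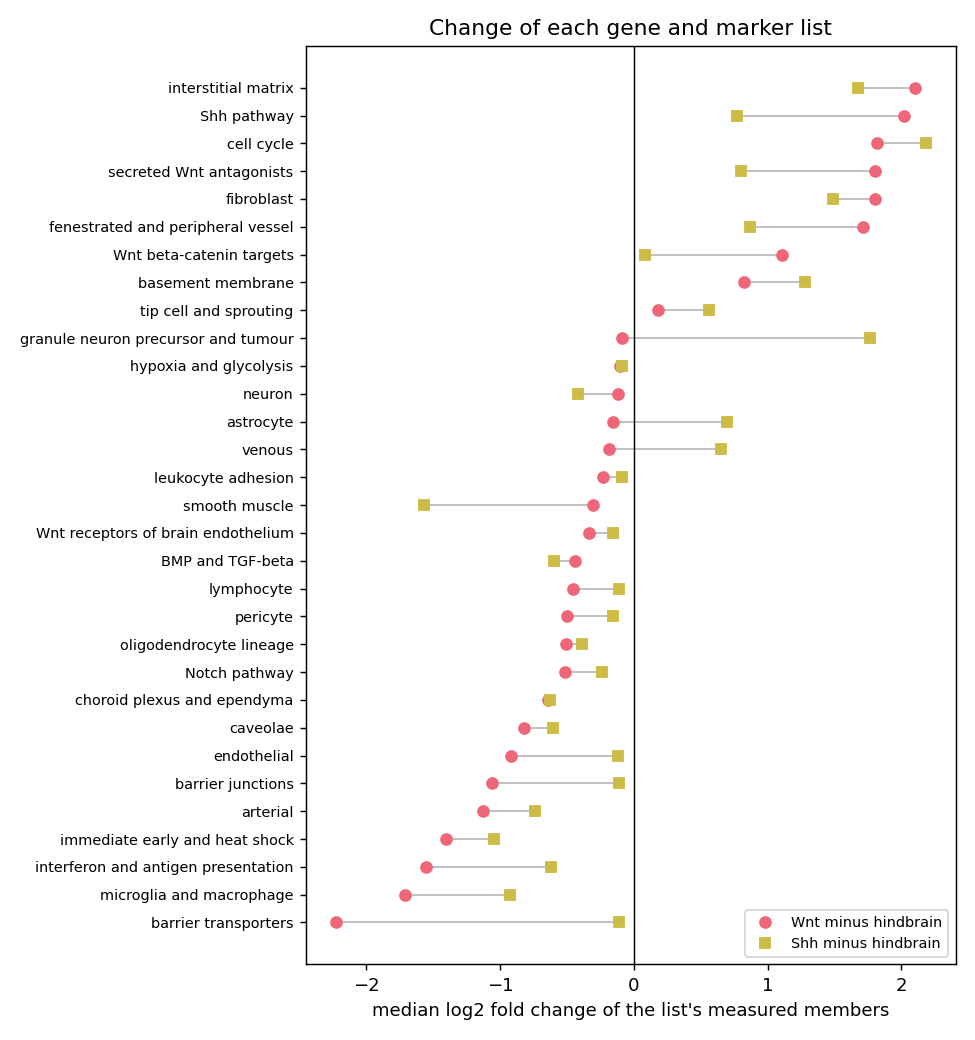
Median log2 fold change of the measured members of each of the 31 lists in Wnt against hindbrain (circles) and Shh against hindbrain (squares), ordered by the former, with a line joining the values of a list. Barrier transporters stand at -2.23 in Wnt and -0.11 in Shh, and precursor markers at -0.093 and 1.76; relative to the endothelial markers, Wnt values move up by 1.06 and Shh values by 0.183, which turns the signs of 16 and 8 medians, that of the barrier transporters in Shh among the latter.

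Of 22180 genes, 4203 were higher and 4182 lower in Shh than in hindbrain arrays, 919 and 635 of them by at least 2-fold. The share of higher genes among those called was 50.1%, against 49.2% with each array shifted to the same median and 75.7% relative to the endothelial marker mean. Large rises without overlap between the groups were also seen for Gpnmb (4.73 ± 0.41, adjusted p = 2.77e-09) and Atp6v0d2 (4.70 ± 0.42, adjusted p = 4.39e-09), genes of lysosomes and of a proton pump, and for Prnd (4.50 ± 0.28) and Scgb3a1 (4.14 ± 0.33). The histone genes H1f5 (5.38 ± 0.32) and H2bc12 (4.27 ± 0.29) rose too, values that are uncertain because histone genes have close copies. The largest falls included the microglial Siglech (-4.83 ± 0.27, adjusted p = 1.7e-12) and Slc2a5 (-4.30 ± 0.20), Gpr165 (-3.85 ± 0.46), Il1a (-3.78 ± 0.49) and Slc26a10 (-3.73 ± 0.11). Hindbrain means of Atp6v0d2 and H1f5 and Shh means of Slc2a5 and Gpr165 lay within the range of the ERCC controls. Camera called 16 of 31 lists with the preset correlation (9 up, 7 down), 0 with an estimated correlation and 10 with an estimated correlation at an unadjusted p under 0.05, and fry called 24. With the genes under the median level left out, 2645 genes were lower, and with the endothelial marker mean as a covariate Cdh5 (0.20, adjusted p = 0.00735) passed the test while the calls of Cdkn2c (0.35, adjusted p = 0.0651) and Kl (-1.43, adjusted p = 0.0523) ended. Cdh5 is itself among the averaged markers.

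The third comparison sets the tumour groups against each other. Most barrier transporters (21 of 24) and junction genes (9 of 14) were lower in Wnt than Shh arrays, among them those of a lipid transporter and of a tight junction protein, Mfsd2a (-3.19 ± 0.35, adjusted p = 6.49e-08) and Cldn5 (-2.08 ± 0.20, adjusted p = 6.73e-09), and Plvap was higher (3.07 ± 0.34, adjusted p = 1.13e-07). Wif1 (6.27 ± 0.29, adjusted p = 2.92e-14) and 11 of 17 targets of beta-catenin were higher in Wnt arrays. Markers of granule neuron precursors (12 of 16), venous (5 of 11) and sprouting genes (13 of 22) were higher in Shh arrays. The calls of these lists by camera were lost with an estimated correlation (adjusted p from 0.135 to 0.372), and relative to the endothelial markers the medians of junction (0.15), venous (0.27) and sprouting genes (0.20) turned to higher in Wnt.

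Of 24 barrier transporters, 0 rose, 21 fell and 3 did not pass the test, with a median of -1.93 (adjusted p = 1.25e-17, and adjusted p = 0.135 with an estimated correlation). Slc22a8 (-4.26 ± 0.30), Slc40a1 (-4.32 ± 0.23), Slc16a1 (-4.01 ± 0.21), Slc38a5 (-3.91 ± 0.31), Abcb1a (-1.65 ± 0.23) and Slc2a1 (-1.21 ± 0.19) were lower in Wnt. Of 14 barrier junction genes, 2 rose, 9 fell and 3 did not pass the test, with a median of -0.72 (adjusted p = 0.00131, and adjusted p = 0.372 with an estimated correlation). Lsr (-2.17 ± 0.22) was lower. Of 15 genes of fenestrated and peripheral vessels, 6 rose, 1 fell and 8 did not pass the test, with a median of 0.41 (adjusted p = 0.0488, and adjusted p = 0.381 with an estimated correlation). Aqp1 (3.07 ± 0.42) was higher. The call of that list was lost without hindbrain replicate 2 (0.41), Shh replicates 1 (0.35), 5 (0.34), 6 (0.39), 7 (0.38), 8 (0.38), Wnt replicates 4 (0.35), 5 (0.29), 6 (0.49), 7 (0.55). Of 8 genes of caveolae, 2 rose, 2 fell and 4 did not pass the test (3 up and 3 down adjusted over the list alone), with a median of 0.015 (adjusted p = 0.887), while the mean was 0.0031 and the set test pointed down. Of 17 Wnt beta-catenin targets, 11 rose, 3 fell and 3 did not pass the test (12 up and 3 down adjusted over the list alone), with a median of 0.56 (adjusted p = 0.000619, and adjusted p = 0.135 with an estimated correlation). Notum (4.51 ± 0.22), Rnf43 (3.93 ± 0.19) and Axin2 (1.93 ± 0.12) were higher and Foxq1 (-3.23 ± 0.20) and Ppard (-1.53 ± 0.11) lower. Lef1 (0.32 ± 0.12, adjusted p = 0.0441) was higher, a call lost without hindbrain replicates 3 (0.32), 4 (0.32), 5 (0.32), 7 (0.32), Shh replicates 1 (0.31), 2 (0.25), 7 (0.27), 8 (0.28), Wnt replicates 1 (0.30), 2 (0.32), 3 (0.33), 4 (0.33), 5 (0.29), 8 (0.27). Of 9 Wnt receptors of brain endothelium, 1 rose, 3 fell and 5 did not pass the test, with a median of -0.14 (adjusted p = 0.184). Of 13 secreted Wnt antagonists, 7 rose, 1 fell and 5 did not pass the test (7 up and 3 down adjusted over the list alone), with a median of 1.63 (adjusted p = 0.0064, and adjusted p = 0.135 with an estimated correlation). Sostdc1 (4.78 ± 0.35) and Dkk1 (2.08 ± 0.36) were higher and Draxin (-2.66 ± 0.24) lower. Of 10 Shh pathway genes, 7 rose, 2 fell and 1 did not pass the test, with a median of 1.22 (adjusted p = 0.00241, and adjusted p = 0.372 with an estimated correlation). Hhip (2.64 ± 0.32) was higher and Gli1 (-1.57 ± 0.32) lower.

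Of 22 genes of tip cells and sprouting, 3 rose, 13 fell and 6 did not pass the test (3 up and 14 down adjusted over the list alone), with a median of -0.67 (adjusted p = 0.00143, and adjusted p = 0.372 with an estimated correlation). Apln (-2.72 ± 0.24) and Angpt2 (-1.84 ± 0.34) were lower. Of 13 Notch pathway genes, 3 rose, 7 fell and 3 did not pass the test, with a median of -0.45 (adjusted p = 0.0537, and adjusted p = 0.491 with an estimated correlation), and it passed the test at the preset correlation without Shh replicate 8 (-0.47), Wnt replicates 2 (-0.46), 3 (-0.47), 4 (-0.46), 5 (-0.50). Hey2 (1.59 ± 0.15) was higher. Of 17 BMP and TGF-beta genes, 7 rose, 3 fell and 7 did not pass the test (7 up and 4 down adjusted over the list alone), with a median of -0.14 (adjusted p = 0.236), while the mean was 0.38 and the set test pointed up. Of 14 arterial genes, 4 rose, 3 fell and 7 did not pass the test, with a median of -0.021 (adjusted p = 0.761). Of 11 venous genes, 0 rose, 5 fell and 6 did not pass the test (0 up and 6 down adjusted over the list alone), with a median of -0.60 (adjusted p = 0.000802, and adjusted p = 0.347 with an estimated correlation). Ackr1 (-4.04 ± 0.32) was lower. Of 12 genes of leukocyte adhesion, 2 rose, 6 fell and 4 did not pass the test, with a median of -0.44 (adjusted p = 0.0873). Of 17 basement membrane genes, 1 rose, 8 fell and 8 did not pass the test (1 up and 9 down adjusted over the list alone), with a median of -0.36 (adjusted p = 0.00458, and adjusted p = 0.395 with an estimated correlation). Nid1 (-0.97 ± 0.18) was lower. Of 18 genes of the interstitial matrix, 8 rose, 2 fell and 8 did not pass the test (9 up and 3 down adjusted over the list alone), with a median of 0.61 (adjusted p = 0.0099, and adjusted p = 0.491 with an estimated correlation). Tnc (2.75 ± 0.36) was higher and Lum (-1.84 ± 0.29) lower. Of 26 cell cycle genes, 0 rose, 2 fell and 24 did not pass the test (0 up and 1 down adjusted over the list alone), with a median of -0.23 (adjusted p = 0.0994, and adjusted p = 0.743 with an estimated correlation), and it passed the test at the preset correlation without Shh replicates 3 (-0.34), 6 (-0.33), Wnt replicate 2 (-0.34). Of 17 genes of hypoxia and glycolysis, 4 rose, 2 fell and 11 did not pass the test, with a median of 0.063 (adjusted p = 0.381). Vegfa (1.89 ± 0.21) was higher. Of 21 genes of interferon response and antigen presentation, 0 rose, 16 fell and 5 did not pass the test (1 up and 18 down adjusted over the list alone), with a median of -0.87 (adjusted p = 4.1e-06, and adjusted p = 0.372 with an estimated correlation). Gbp3 (-1.42 ± 0.23) was lower. Of 16 immediate early and heat shock genes, 1 rose, 2 fell and 13 did not pass the test, with a median of -0.093 (adjusted p = 0.574), while the mean was 0.0045 and the set test pointed down.

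Markers of other cells differed as well. Of 16 markers of granule neuron precursors, 0 rose, 12 fell and 4 did not pass the test (0 up and 13 down adjusted over the list alone), with a median of -1.57 (adjusted p = 1.67e-08, and adjusted p = 0.135 with an estimated correlation). Dcx (-3.76 ± 0.25) and Nhlh1 (-3.56 ± 0.29) were lower, with Wnt means within the range of the ERCC controls. Of 12 pericyte markers, 0 rose, 7 fell and 5 did not pass the test (0 up and 8 down adjusted over the list alone), with a median of -0.48 (adjusted p = 0.00433, and adjusted p = 0.461 with an estimated correlation). Atp13a5 (-4.11 ± 0.58) was lower. Of 6 smooth muscle markers, 5 rose, 0 fell and 1 did not pass the test, with a median of 1.09 (adjusted p = 0.00458, and adjusted p = 0.135 with an estimated correlation). Cnn1 (1.66 ± 0.30) was higher. Of 10 fibroblast markers, 4 rose, 2 fell and 4 did not pass the test (4 up and 3 down adjusted over the list alone), with a median of -0.0078 (adjusted p = 0.236), while the mean was 0.64 and the set test pointed up. Ogn (4.03 ± 0.32) and Fmod (3.45 ± 0.27) were higher. Of 20 microglia and macrophage markers, 2 rose, 6 fell and 12 did not pass the test, with a median of -0.61 (adjusted p = 0.0365, and adjusted p = 0.648 with an estimated correlation). Ms4a7 (-1.74 ± 0.49) and Cd68 (-1.66 ± 0.35) were lower and Tmem119 (0.97 ± 0.22) higher. The call of that list was lost without Shh replicates 1 (-0.51), 2 (-0.44), 3 (-0.52), 7 (-0.55), Wnt replicates 3 (-0.52), 5 (-0.43). Of 9 lymphocyte markers, 0 rose, 6 fell and 3 did not pass the test, with a median of -0.34 (adjusted p = 0.0243, and adjusted p = 0.388 with an estimated correlation). Of 13 neuron markers, 5 rose, 2 fell and 6 did not pass the test, with a median of 0.19 (adjusted p = 0.512). Snap25 (-3.19 ± 0.38) was lower. Of 12 astrocyte markers, 4 rose, 6 fell and 2 did not pass the test, with a median of -0.63 (adjusted p = 0.236). Gfap (-2.53 ± 0.32) was lower. Of 14 oligodendrocyte lineage markers, 1 rose, 4 fell and 9 did not pass the test, with a median of -0.087 (adjusted p = 0.12). Olig2 (-2.54 ± 0.33) was lower. Of 8 choroid plexus and ependyma markers, 2 rose, 0 fell and 6 did not pass the test, with a median of 0.024 (adjusted p = 0.234).

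In Wnt against Shh arrays, 3996 genes were higher and 3950 lower, 1038 and 773 of them by at least 2-fold. With each array shifted to the same median, 4978 were higher and 3030 lower, so the share of higher genes moved from 50.3% to 62.2%. Mybpc1 (6.34 ± 0.35, adjusted p = 4.26e-13), Wnt16 (6.22 ± 0.23, adjusted p = 4.5e-16) and A2m (5.73 ± 0.44, adjusted p = 2.24e-10) rose most beside Wif1, followed by Otop3 (5.49 ± 0.15), P2rx2 (5.46 ± 0.29), Fndc3c1 (5.27 ± 0.31) and Cdh6 (5.11 ± 0.26). Far2 (-4.53 ± 0.33, adjusted p = 9.94e-11), Atp6v0d2 (-4.38 ± 0.42, adjusted p = 8.65e-09) and Ccl11 (-3.85 ± 0.26) were among the lowest, and the dimmer means of Fndc3c1 and Atp6v0d2 lay within the range of the ERCC controls. The sort antigens were lower in Wnt, with Cdh5 (-0.48 ± 0.11) and Eng (-0.62 ± 0.10), but higher relative to the endothelial markers (0.39 and 0.25). Both are among those markers, so members that fall less than the average turn up by construction. Camera called 17 lists with the preset correlation (6 up, 11 down), 0 with an estimated correlation and 5 with an estimated correlation at an unadjusted p under 0.05, and fry called 25. With the endothelial marker mean as a covariate, 2009 genes were higher and 1881 lower, the sign of Cdh5 (0.12, adjusted p = 0.371) turned, and the calls of Cdkn2c (0.34, adjusted p = 0.341), Eng (-0.039, adjusted p = 0.778), Slc2a1 (-0.52, adjusted p = 0.167), Abcb1a (-0.53, adjusted p = 0.123), Lef1 (0.45, adjusted p = 0.13), Angpt2 (-0.64, adjusted p = 0.368), Nid1 (-0.13, adjusted p = 0.718), Atp13a5 (-2.29, adjusted p = 0.061), Cnn1 (1.29, adjusted p = 0.069) and Tmem119 (0.025, adjusted p = 0.967) ended, as did those of the lists of barrier junctions, Shh pathway, tip cell and sprouting, venous, basement membrane, endothelial, pericyte and lymphocyte genes. Relative to the endothelial marker mean every log2 fold change is larger by 0.873, which turns the sign of 18 list medians, among the lists called those of barrier junctions, tip cell and sprouting, venous, basement membrane, interferon and antigen presentation, pericyte, microglia and macrophage and lymphocyte genes, and makes 97.8% of the called genes higher.

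Changes against hindbrain were partly shared by the tumour groups, which were set against the same hindbrain arrays. 2543 genes were higher and 2648 lower in both, where independent lists of these sizes would share 976 and 922. Of these, 956 and 854 differed between Wnt and Shh by the direct test, and 492 and 470 changed by at least 2-fold in both. Another 423 genes were called in opposite directions, 200 of them higher in Wnt. In 100 simulations of unchanged tumour groups against the same hindbrain arrays, 0 genes were higher and 0 lower in both in every one, but at most 5 and 0 genes were called in Wnt and Shh at all, so these counts do not tell how much of the sharing comes from the shared arrays. With the hindbrain arrays split into separate sets of 4, the median over 70 splits was 1835.5 higher genes (1728 to 1985) and 1847 lower (1773 to 1917). Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.585 and a covariance of 0.251, against 0.519 and 0.0108 in the simulations. The correlation lies within the simulated range of 0.207 to 0.727 that shared hindbrain arrays alone give, and the covariance lies above its range of 0.00319 to 0.0208. With separate hindbrain sets of 4, the median correlation over the 70 splits was still 0.559 (0.536 to 0.581). The median covariance was 0.244 (0.235 to 0.25). Both argue against shared hindbrain arrays as the whole source of the correlation. With the endothelial marker mean as a covariate, 1255 genes were higher and 1408 lower in both.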

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

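The tests on barrier, antagonist, precursor, cell cycle and microglial genes below were chosen after the list values had been seen, and the splits of the arrays before theirs, those of the list counts after the list test had been tried on simulated data. The bound for the microglial markers is the one written first, more than 10 of 20, and a lower one set after the count was seen was dropped. The demand that rho also pass after adjustment was added after the correlations were seen.

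Most barrier transporters were lower in Wnt arrays. Dilution by RNA of other cells would lower barrier and endothelial genes alike, but the barrier mean minus the endothelial mean differed by -1.24 (two-sided exact permutation p = 0.000155, the smallest possible) and by -1.66 among members of matched level, which argues against dilution alone. With the endothelial marker mean as a covariate the median was -1.37 in place of -2.23. Limma still called 17 of 24 transporters lower, 1 higher and 6 not. The list's call (adjusted p = 2.2e-09) was lost with an estimated correlation (adjusted p = 0.149). Every Wnt array lay below all others in marker mean, so the fit cannot tell content from group. Content may cause part of the fall. A difference of the tumour vessels themselves and the handling of tissue before lysis, which goes with the group, stay open and untested.

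Most Wnt antagonists, beta-catenin targets, Shh pathway and cell cycle genes were higher in Wnt arrays, most precursor and cell cycle genes in Shh arrays. Tumour cells, which the sort should remove, are a candidate source. Means were 12.87 ± 0.18 for Wif1 in Wnt and 8.17 ± 0.86 for Dcx in Shh arrays (log2, SD, n = 8). Over the 8 Wnt arrays the rising antagonists went down with the endothelial marker mean, r = -0.758 (exact permutation p = 0.0332, adjusted 0.0415; rho = -0.833, exact permutation p = 0.0154, adjusted 0.0256; r = -0.863 without the 2 farthest arrays), and over the 8 Shh arrays the rising precursor genes did, r = -0.875 (exact permutation p = 0.000298, adjusted 0.00149; rho = -0.929, exact permutation p = 0.00223, adjusted 0.00558; r = -0.861 without the 2 farthest arrays). In Shh arrays cell cycle genes tracked precursor genes, r = 0.913 and rho = 0.976 (exact permutation p = 0.00107 and 0.000397, adjusted 0.00267 and 0.00198). Without the 2 farthest arrays they gave r = 0.814. With the antagonists in Wnt arrays they gave r = 0.835 and rho = 0.619 (exact permutation p = 0.00764 and 0.115, adjusted 0.0127 and 0.144). Without the 2 farthest arrays r was 0.479, so this relation rests on them and stays open. With the microglial one these are 5 relations. Those not left open go with RNA of tumour or other non-endothelial cells. Antagonists were not listed as tumour markers, and fibroblasts, whose markers mostly rose, and dividing endothelium were not tested.

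Most microglial and immediate early genes were lower in tumour arrays. In Shh against hindbrain, 8 of 20 microglial markers lay over 3 standard errors from the list's median, against 0.12 expected if all fell alike. Though under the bound, this argues against a uniform fall (P2ry12 -2.94, Ms4a7 2.77). A smaller share of microglia stays open, as the list's macrophage genes need not fall too. Whether immediate early RNA may come from microglia cannot be told apart from other sources, since over 8 hindbrain arrays r = 0.554 (exact permutation p = 0.158, adjusted 0.158; rho = 0.548, exact permutation p = 0.171, adjusted 0.171; r = -0.0165 without the 2 farthest arrays). A changed state of the myeloid cells was not tested.

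Other splits of the 16 arrays of each comparison were tested, 100 each with the real one. Chance is unlikely for the genes called (1 of 100 splits as large in each). Wnt against hindbrain called 10040, and at most 6168 in another split. Shh against hindbrain gave 8385 and 5081, and Wnt against Shh 7946 and 4526. For the number of lists called, the real split of Wnt against hindbrain called the most, 21 against at most 20 in another (1 split as large). That does not exclude chance, since another split came so close and camera at the preset correlation is weak. Nor is chance excluded for the list counts in Shh against hindbrain (16 and 21, 13 splits as large) or Wnt against Shh (17 and 18, 6 splits as large).

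Single arrays stood apart from the rest of their group in 42 of 540 groups of 8 tested by Dixon's ratio of the gap to the range, where chance gives about 1 in 20, or 27. The ratios were Bmp4 0.589, Car4 0.535, Cldn5 0.552, Col1a1 0.566, Cxcl12 0.562, Nid1 0.534, endothelial list mean 0.533 in hindbrain replicate 6, Adm 0.666, Angpt2 0.619, Ccl11 0.687, Ccnd1 0.67, Edn1 0.655, Tecrl 0.849 in Wnt replicate 4, Mbp 0.589, Snap25 0.527, Vtn 0.55, neuron list mean 0.56, astrocyte list mean 0.531 in Shh replicate 3. Further ratios were Ifit1 0.597, Mx2 0.553, Slc40a1 0.621, interferon and antigen presentation list mean 0.593 in Wnt replicate 2, Gli3 0.538, Zic2 0.542, smooth muscle list mean 0.572 in Shh replicate 6, Pdgfra 0.593, Vegfa 0.55, oligodendrocyte lineage list mean 0.542 in Wnt replicate 3, Fmod 0.655, Pcna 0.611 in hindbrain replicate 8, Siglech 0.578, hypoxia and glycolysis list mean 0.711 in Shh replicate 2, Wif1 0.66, Wnt16 0.598 in Shh replicate 4, Clic6 0.563, Kl 0.621 in Shh replicate 5, Gli1 0.607, Slc26a10 0.535 in Wnt replicate 1, Atp13a5 0.793, Sostdc1 0.538 in Wnt replicate 5, Mobp 0.573 in hindbrain replicate 7, Marveld3 0.544 in Shh replicate 7. Hindbrain replicate 6 held 7 of them and Wnt replicate 4 held 6.

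Some genes were called in opposite directions in the Wnt and Shh arrays against hindbrain, and the direct test of Wnt minus Shh gave log2 differences of 1.93 for Axin2, -1.17 for Cd3g, 5.11 for Cdh6, 3.45 for Fmod, 1.59 for Hey2, 1.20 for Marveld3, 4.51 for Notum, 4.03 for Ogn, -1.53 for Ppard, -4.01 for Slc16a1, -3.91 for Slc38a5. The hindbrain and Wnt means of Cd3g (4.96 and 4.29) lay within the range of the ERCC controls, so its directions are uncertain. Probe sets without a gene symbol, which enter no gene test, were called in number as well, 2997 in Wnt against hindbrain, 2592 in Shh against hindbrain and 2444 in Wnt against Shh, of 15820 tested.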

How the results depend on the processing

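Values relative to endothelial markers, the fit without Wnt arrays 1 and 8 and the covariate together with an estimated correlation were chosen after the results had been seen, and the other settings before. Counts of called genes stayed within 1.5 times under every other setting than those named next. With the endothelial marker mean as a covariate, 2288 genes were higher and 1976 lower in Wnt than hindbrain, 2009 and 1881 in Wnt than Shh, and 1255 and 1408 in both tumour groups, and the cause was not tested. With the genes under the median level left out, 2645 were lower in Shh, since fewer genes were tested. An estimated correlation left 1, 0 and 0 lists called by camera in Wnt against hindbrain, Shh against hindbrain and Wnt against Shh (6, 10, 5 at an unadjusted p under 0.05, and 26, 24, 25 by fry), and with the covariate too 4, 0 and 0 (8, 12, 7 at an unadjusted p under 0.05). Relative to endothelial markers, 20162 were higher and 564 lower in Wnt than hindbrain, 1040 lower in Shh, 19698 and 448 in Wnt than Shh, and 372 lower in both, since this adds 1.06, 0.183 and 0.873 to every log2 change of the 3 comparisons. It turned the direction of 13 of the 238 gene values printed here, 9 of which then passed the test and 8 of which had been called the other way, and ended the calls of Slc2a1 (-0.35), Cav1 (-0.27), Tinagl1 (-0.34) and Cd79b (-0.011) in Wnt against hindbrain, Cdkn2c (0.71) in Shh against hindbrain and Slc2a1 (-0.34), Gli1 (-0.70), Nid1 (-0.092), Ms4a7 (-0.86) and Cd68 (-0.79) in Wnt against Shh. The replicate block gave 5064 and 4787, 4152 and 4060, and 3920 and 3894 genes higher and lower in the 3 comparisons. Median shifts kept 9020, 7931 and 7026 of the calls in their direction, and the median of all genes moved by less than 0.1. The covariate ended the calls of 28 of these gene values.

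Directions turned as follows, and the cause was not tested except for single genes relative to endothelial markers, which the added constants turn: with quantile normalization, astrocyte -0.16 in Wnt against hindbrain, Cldn5 -0.036, lymphocyte -0.074 in Shh against hindbrain; with arrays shifted to the same median, astrocyte -0.090 in Wnt against hindbrain; with the genes under the median level left out, granule neuron precursor and tumour 0.64 in Wnt against hindbrain, leukocyte adhesion -0.10, oligodendrocyte lineage 0.86 in Shh against hindbrain, neuron -0.021 in Wnt against Shh; with array weights, Pik3ca -0.0047 in Wnt against hindbrain, lymphocyte -0.069 in Shh against hindbrain; with only the compared groups fitted, hypoxia and glycolysis -0.11 in Wnt against hindbrain; with a block by replicate number (replicate block), venous -0.19 in Wnt against hindbrain; with the endothelial marker mean as a covariate (lists also with an estimated correlation), Ptch1 -0.16, Cdh5 0.32, Tinagl1 0.24, Vtn 0.21, venous 0.79, endothelial 0.18, pericyte 0.16, astrocyte 0.081, choroid plexus and ependyma -0.29 in Wnt against hindbrain, barrier transporters 0.078, endothelial 0.041, pericyte 0.056 in Shh against hindbrain, Cdh5 0.12, caveolae 0.49, Wnt receptors of brain endothelium 0.088, Notch pathway -0.058, arterial 0.47, basement membrane 0.13, immediate early and heat shock 0.17, pericyte 0.15 in Wnt against Shh; with fry in place of camera, venous -0.19, hypoxia and glycolysis -0.11, granule neuron precursor and tumour -0.093 in Wnt against hindbrain; with values relative to endothelial markers, Ctnnb1 0.82, Cdh5 0.65, Eng 0.31, Lef1 0.68, Adgra2 0.064, Pcna 0.73, astrocyte 0.90 in Wnt against hindbrain, Ptch1 0.043, Ctnnb1 0.026, Eng 0.060 in Shh against hindbrain, Ctnnb1 0.79, Pik3ca 0.79, Cdh5 0.39, Eng 0.25, caveolae 0.89, hypoxia and glycolysis 0.94, fibroblast 0.87, neuron 1.07 in Wnt against Shh; with Wnt arrays 1 and 8 left out, Ptch1 -0.053, Pik3ca -0.0059, venous 0.11, hypoxia and glycolysis -0.094 in Wnt against hindbrain, caveolae 0.078, arterial 0.11 in Wnt against Shh. Cdh5, Eng and the endothelial list enter the marker mean, so their turns follow in part from the reference. List values are medians and the direction is that of the set test, which relative to endothelial markers pointed down for the astrocyte, hypoxia, fibroblast and neuron lists although their medians were above 0. Of these, Cdh5 (0.32, adjusted p = 0.0247) and the venous list in Wnt against hindbrain and caveolae in Wnt against Shh passed the test under the covariate (the lists with adjusted p = 0.299 and 0.148 with an estimated correlation, so not passing there), and 9 gene values and, at the preset correlation, the astrocyte list relative to endothelial markers; the others did not pass it.

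When single arrays were left out, the ranges of the counts were 16 to 19 for gene lists called in Shh minus hindbrain, 21 to 21 for gene lists called in Wnt minus hindbrain, 15 to 19 for gene lists called in Wnt minus Shh, 2266 to 2632 for genes higher in both tumour groups than hindbrain, 3869 to 4281 for genes higher in Shh than hindbrain, 4888 to 5292 for genes higher in Wnt than hindbrain, 3752 to 4083 for genes higher in Wnt than Shh, 2468 to 2704 for genes lower in both tumour groups than hindbrain, 3822 to 4257 for genes lower in Shh than hindbrain, 4601 to 4954 for genes lower in Wnt than hindbrain, 3649 to 4001 for genes lower in Wnt than Shh. Directions turned within the ranges of astrocyte -0.26 to -0.054, Pik3ca -0.024 to 0.033, venous -0.31 to -0.044, hypoxia and glycolysis -0.16 to -0.040, Ptch1 -0.095 to 0.17 in Wnt against hindbrain, Cldn5 -0.031 to 0.068, lymphocyte -0.15 to -0.048 in Shh against hindbrain, caveolae -0.027 to 0.057 in Wnt against Shh. Signal over background limits genes whose means lie within the range of the ERCC controls. Calls also ended for fenestrated and peripheral vessel (0.41) in Wnt against Shh with the mean of the probe sets of a gene, Cdkn2c (0.49) in Shh against hindbrain, Lef1 (0.27), fenestrated and peripheral vessel (0.41) in Wnt against Shh with quantile normalization, Pcna (-0.26) in Wnt against hindbrain, fenestrated and peripheral vessel (0.47) in Wnt against Shh with arrays shifted to the same median, basement membrane (0.82), oligodendrocyte lineage (-0.39) in Wnt against hindbrain, fenestrated and peripheral vessel (0.41), microglia and macrophage (-0.62) in Wnt against Shh with the genes under the median level left out, lymphocyte (-0.37), oligodendrocyte lineage (-0.51) in Wnt against hindbrain, fenestrated and peripheral vessel (0.41), microglia and macrophage (-0.61), lymphocyte (-0.33) in Wnt against Shh with the genes of lowest level (bottom quartile) left out, Lef1 (0.28), microglia and macrophage (-0.50) in Wnt against Shh with array weights, Kl (-1.60) in Shh against hindbrain, Lef1 (0.32) in Wnt against Shh with only the compared groups fitted, Lef1 (0.32), fenestrated and peripheral vessel (0.41) in Wnt against Shh with a block by replicate number (replicate block), microglia and macrophage (-0.61) in Wnt against Shh with fry in place of camera, Lef1 (0.24) in Wnt against Shh with Wnt arrays 1 and 8 left out. Relative to endothelial markers, 7 lists lost an upward and 2 a downward call. Calls not made before appeared, upward and downward, for 0 and 1 genes with array weights, 0 and 2 lists with arrays shifted to the same median, 3 and 1 lists and 1 and 0 genes with the endothelial marker mean as a covariate, 7 and 15 lists with fry in place of camera, 4 and 17 lists and 0 and 2 genes with single arrays left out (counted per array), 1 and 0 lists with the genes under the median level left out, 1 and 0 lists and 1 and 1 genes with only the compared groups fitted, 0 and 3 lists and 0 and 1 genes with quantile normalization, 1 and 15 lists and 3 and 0 genes with values relative to endothelial markers and 0 and 2 lists with a block by replicate number (replicate block).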

Other observations

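The tests above on cell sources were chosen after the values had been seen. None was run for these values, so tumour cells stay open as their source. Of 8 choroid plexus and ependyma markers, 2 rose and 5 fell in Wnt against hindbrain. The transcription factor Otx2 (4.93 ± 0.46, adjusted p = 3.08e-09) and the chloride channel Clic6 (3.68 ± 0.35, adjusted p = 3.21e-09) rose. Among the fallers was Ttr (-3.20 ± 0.91, adjusted p = 0.00499). The groups did not overlap for Otx2 and Clic6 but did for Ttr, whose hindbrain arrays varied widely (9.27 ± 2.66 against 6.07 ± 0.30 in Wnt arrays, log2, SD, n = 8), so its fall rests on part of the hindbrain arrays. Otx2 (3.79 ± 0.46, adjusted p = 4.4e-07) and Clic6 (4.04 ± 0.35, adjusted p = 1.44e-09) were also higher in Wnt than Shh arrays. The call of Ttr ended with the endothelial marker mean as a covariate (-1.89, adjusted p = 0.515).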
